A study of Mus musculus with 2 samples.

How the data were processed

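Total RNA was extracted from 4T1 tumours, grown from a mouse mammary carcinoma cell line used as a model of metastatic breast cancer, and sequenced in bulk. There were 2 libraries, 1 from the tumour of the degrader arm and 1 from the control arm. Per the labels, each library was made from 1.5 µg of RNA with a kit of the AccuraCode series, and the treated tumour came from batch 1 and the control tumour from batch 2. The library of each arm was assigned from the treatment field of the labels, and its column in the table through the sheet deposited for that sample, whose single column of values carries the same name.

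The authors deposited a table of counts per gene, with Ensembl gene identifiers and symbols, in 34290 rows. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10. The aligner, the counting tool, the handling of strand and of reads shared by several genes, and whether molecular identifiers were collapsed are not given in the sources used here. The deposited counts are whole numbers in 34259 rows. The other 31 rows, which stand together at the top of the table and hold autophagy genes, were not on the count scale: 30 of them hold at least 1 value that is not whole. In all 31, both values were whole multiples, within 1e-06 of a step, of a step shared by both libraries, equal to 983 divided by a whole number of at most 100. Among the other base numbers tried between 500 and 2000 that are not multiples of this one, none covered more than 1 of the rows. The steps took 13 different values, from 9.83 to 983. What was done to these rows is not given in the sources used here, so they were kept out of library totals, scaling, counts of genes and gene lists, and their deposited values are reported on their own. They made up 6.28% of the treated and 11.2% of the control column. A further 7 columns of values, some of which share a letter with the columns used, were not tied to a sample by a sheet of their own and were not used. What they hold is not given in the sources used here. A second deposited sheet holds 34250 of the genes and was used as an alternative.

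The whole-number rows summed to 3824323 counts in the treated and 2252214 in the control library, with 17987 and 16634 genes detected. Libraries were scaled by the trimmed mean of M values (TMM), written out from its formula with 30% of log ratios and 5% of abundances trimmed at each end. The scaling factors were 1.01 and 0.989. Counts were expressed as CPM of the scaled totals. 1 count equals 0.259 CPM in the treated and 0.449 CPM in the control library. The log2 ratio of a gene is the treated over the control CPM after a pseudocount of 1 was added to both, which understates the difference of low genes. Folds of single genes were computed from CPM without a pseudocount.

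With 1 library per group there is no spread between replicates, so no test between conditions was run and no p-value is given. Genes were counted by a fixed rule of size, at least 2-fold on the log2 scale among genes with a mean of at least 10 CPM over both libraries. Intervals of folds are exact conditional binomial 95% intervals, intervals of shares are exact Clopper-Pearson 95% intervals, and both cover counting error only, not the variation between tumours. Of 51 gene lists fixed before the data were examined, 43 had at least 5 measured members. The median log2 ratio of each was ranked among those of 10000 random lists of the same size drawn from 20 bins of mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile. Chance alone would give this for about 2.15 of 43 independent lists whose genes vary independently. The random lists draw single genes, whereas genes of a cell type or pathway can vary together between any tumours. More lists than that can then stand apart without a treatment effect. Lists that share genes are not independent.

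The rule for naming genes was also fixed before the data were examined. It took the 10 highest and the 10 lowest log2 ratios, leaving out predicted genes, clones, marked pseudogenes and antigen receptor segments. From each list it took the 2 most abundant members and the 2 with the largest absolute ratio, and from the autophagy lists any member. The alternatives set in advance were 3 other scalings, namely plain library totals, the median of ratios, and totals without mitochondrially encoded, haemoglobin and ribosomal protein genes. They also included pseudocounts of 0.5 and 5, a minimum mean of 1, of 50 or none, a 1.5-fold threshold, random lists not matched on expression, the mean of a list in place of its median, and the second sheet. A correlation was counted as moved when it shifted by 0.05 or more. Keeping the 31 rows, leaving out epidermal gene families, and leaving out list members that epidermis also expresses were added after the data were seen. The fixed plan assumed one unit per table; the 31 rows depart from it.

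The scaling and the rules were tested on simulated data before use. Counts were drawn for 34259 genes from the mean levels and totals of these libraries, with 200 genes changed. In this draw an abundant gene was also raised in the treated library only. It is counted neither among the 200 nor among the unchanged genes. Of the 100 genes changed 4-fold, 98% passed the 2-fold rule, and of the 100 changed exactly 2-fold, 46% did. Among 8246 unchanged genes, 3 passed it by counting noise. All 20 lists planted with a 1.5-fold difference stood apart, as did 1 of 20 lists without one. The simulated lists held genes drawn at random, without genes that vary together and without variation between tumours. Their rate of false calls therefore does not carry over to the fixed lists. Gene positions come from GENCODE M21 on the same genome build, matched by Ensembl identifier for 32236 of the 34290 rows. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.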

Results

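The series compared the transcriptome of a 4T1 tumour treated with a compound that degrades an autophagy-related protein with that of a control tumour. 4T1 is a mouse mammary carcinoma line that forms tumours with many myeloid cells. The degrader was injected 3 times before the treated tumour was collected, and the labels do not name its target. There was 1 library per group, with 3824323 counts for the treated and 2252214 for the control tumour. The treated tumour was batch 1 and the control tumour batch 2, so batch and treatment cannot be told apart. Every value below compares these 2 libraries, not the conditions, and has no replicate check.

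The most marked difference between the libraries was in genes of the stratified epidermis, which were higher in the treated tumour. Of 8865 genes with a mean of at least 10 CPM, 375 were at least 2-fold higher and 222 at least 2-fold lower in the treated library, while 8268 differed by less than 2-fold. The split of 62.8% higher stayed between 60.1% and 67.1% under the other scalings, but with a minimum of 50 CPM it was 51.3%, 81 genes higher and 77 lower. Among the genes at least 2-fold higher, 61 belonged to epidermal families such as keratins, small proline-rich proteins, kallikreins and stefins. None of the 69 measured genes of these families was 2-fold lower. Genes of these families made up 47 of the 72 genes at least 16-fold higher, whereas 4 genes were at least 16-fold lower. The families were set by name patterns after the data were seen, so these counts describe the difference and do not test it. The patterns also take in Krt8 and Krt18 of the 4T1 epithelial list and a stefin of the neutrophil list. The log2 values of the libraries correlated across genes with Pearson's r of 0.89 and Spearman's rho of 0.89, where genes are not independent replicates.

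**Figure D1:**
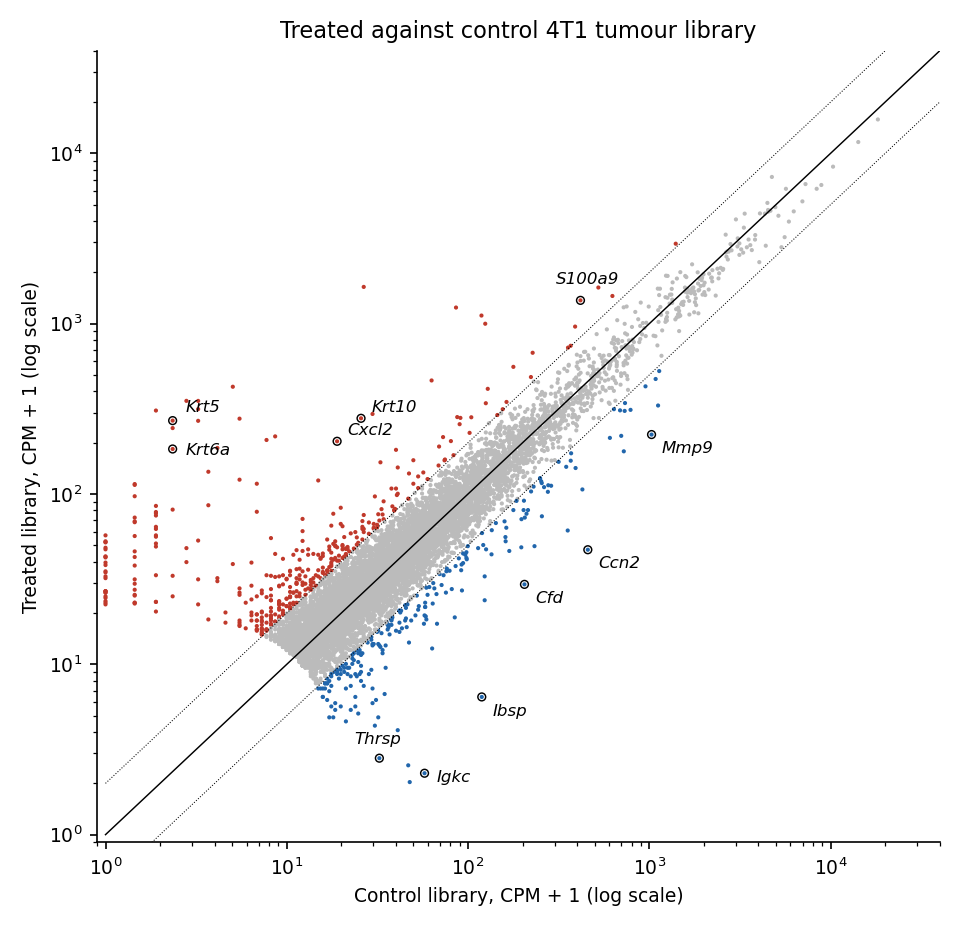
Treated against control library, CPM plus 1 on log axes, for the 8865 genes with a mean of at least 10 CPM. Each point is a gene, red for the 375 at least 2-fold higher and blue for the 222 at least 2-fold lower in the treated library; the solid line marks equal values and the dotted lines 2-fold. Epidermal genes such as Krt5 form a group at the left, with few control counts.

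The 10 highest log2 ratios were those of Sprr2a3, Calm4, Krt5, Krtdap, Dmkn, Krt6b, Stfa3, Krt16, Klk7 and Krt6a. Krt5 (ENSMUSG00000061527, mm10 chromosome 15, 101707070 to 101712898, minus strand), the keratin of basal epithelial cells, had 1038 counts in the treated and 3 in the control library, a ratio of 199.5 with a counting interval of 68.1 to 969. Krtdap (ENSMUSG00000074199, chromosome 7, 30787896 to 30791097, plus strand), which marks differentiating keratinocytes, had 1356 against 5 counts, a ratio of 156 (66.8 to 482). Krt6a, Krt6b and Krt16 are keratins of wounded or activated epidermis, and their ratios were 136 (46.2 to 660), 140 (59.8 to 432) and 119 (51.0 to 368). Klk7, a protease of cornified layers, had 438 against 1 count, a ratio of 253 (45.1 to 9998). Sprr2a3, Stfa3, Krt6a and Krt6b have close paralogs, so how reads were divided among the copies is uncertain. All 12 measured members of the keratinocyte list, of 20 with a row, were more than 2-fold higher. Most of them reached the minimum of 10 CPM only through the treated library, which favours high ratios. The list's median log2 ratio was 5.61, above all 10000 random lists, or 5.48 with the 2 members absent from the control set at 3 control counts. Genes of this list held 0.168% of treated counts (0.164% to 0.172%) and 0.00382% of control counts (0.00305% to 0.00472%). Krt10, the abundant keratin of suprabasal layers, was 11.2-fold higher (8.56 to 15.0).

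The 10 lowest log2 ratios were those of Igkc, Ighg1, Ibsp, Jchain, Thrsp, Hsd11b2, Ccn2, Ptn, Cfd and Adamdec1. The antibody genes Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966, plus strand) and Ighg1 (chromosome 12, 113325240 to 113330523, minus strand) had 5 against 126 and 4 against 104 counts. They were 43.7-fold (18.2 to 137) and 45.1-fold (17.1 to 169) lower in the treated library. Jchain, the joining chain of secreted antibodies, was 29.5-fold lower (13.1 to 82.2). Ibsp, a bone matrix sialoprotein, was 21.7-fold lower (13.9 to 35.7). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683, plus strand), a matricellular protein induced by TGF-beta and YAP, had 178 against 1018 counts and was 9.92-fold lower (8.45 to 11.7). Another 14 genes past the threshold on the higher side and 9 on the lower side had predicted names or were antigen receptor segments.

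Among 43 ranked gene lists, 18 stood apart as higher, 8 as lower and 17 lay within the range of random lists. Of these, 8 higher and 5 lower lists stood apart under every alternative that could rank them. Among them, the erythroid, alternatively activated macrophage, adipocyte, plasma cell and endothelial lists could not be ranked with a minimum of 50 CPM. Lists of 10 or fewer members rest on few genes.

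**Figure D2:**
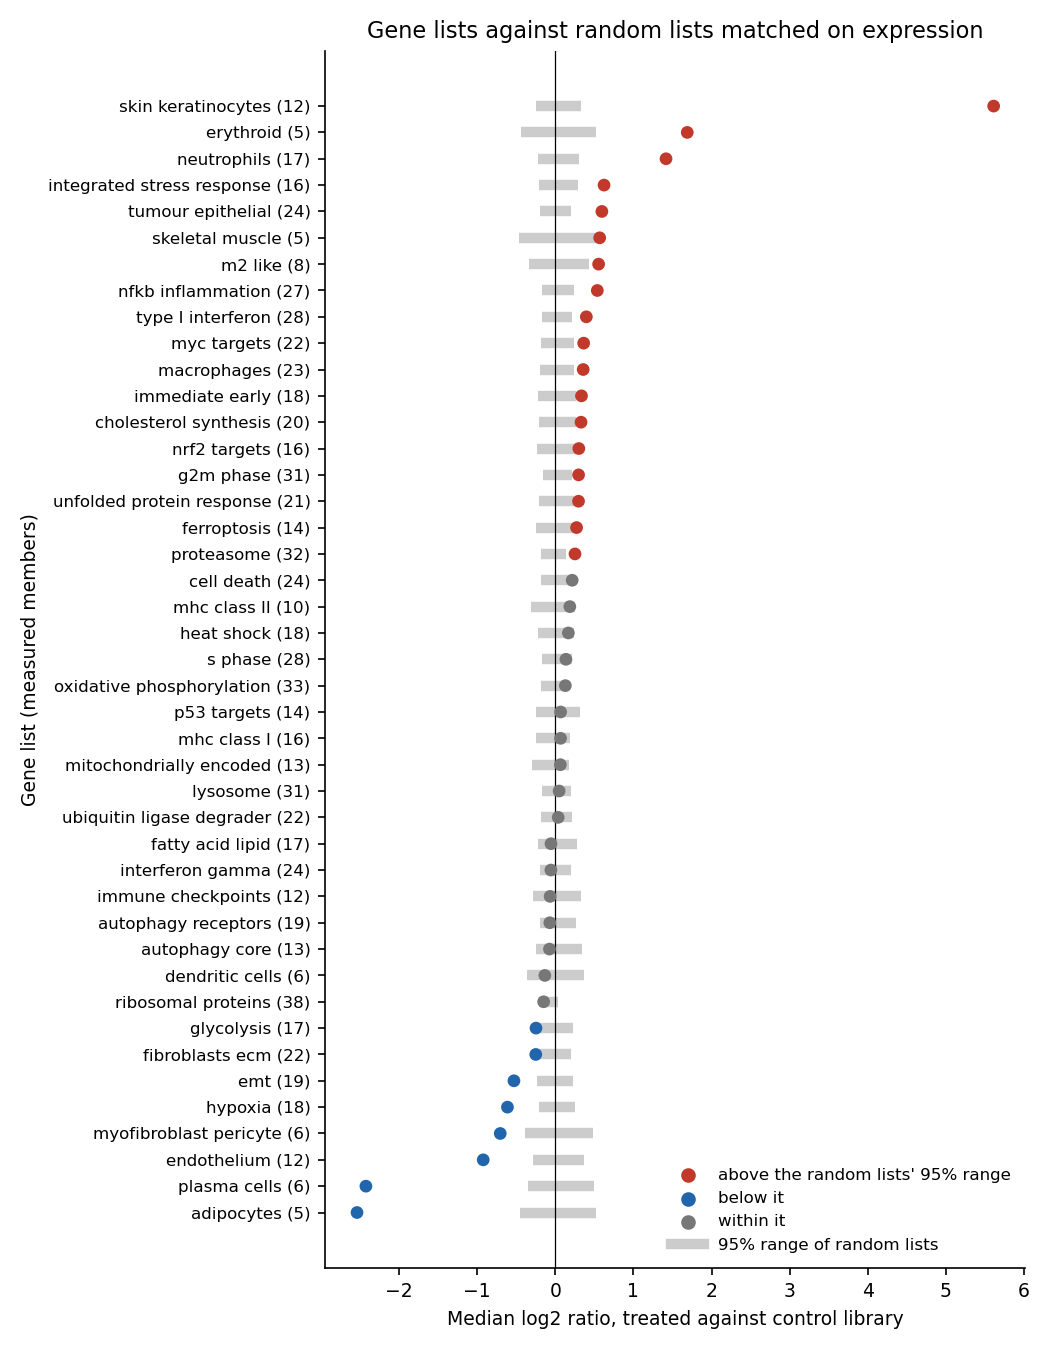
Median log2 ratio (treated against control) of the 43 ranked gene lists, with the number of measured members in parentheses; grey bars are the 95% range of 10000 random lists matched on expression. Keratinocyte genes lie farthest to the right at 5.61, and adipocyte genes farthest to the left at -2.54.

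Autophagy was the process named in the study's title. Among the whole-number rows, the 13 measured members of the core autophagy list had a median log2 ratio of -0.07 (percentile 23.8), and the 19 cargo receptors and regulators had -0.07 (percentile 17.5). None of these 32 genes was 2-fold higher and 1 was 2-fold lower. Sqstm1 (p62), the receptor that links ubiquitinated cargo to autophagosomes, had a ratio of 0.942 (0.854 to 1.04). Gabarap, an ATG8 protein that coats autophagosomes, had a ratio of 0.942 (0.873 to 1.02). Vmp1, needed for autophagosome formation, had 0.909 (0.848 to 0.975). Bnip3, a mitophagy receptor induced by hypoxia, was 2.59-fold lower (2.28 to 2.93), and Stbd1, a glycogen-binding receptor, 2.01-fold lower (1.41 to 2.88) without passing the rule after the pseudocount. Wipi1, an early autophagosome protein, was 1.66-fold higher (1.15 to 2.43).

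The other 31 rows, 25 of them in the core list, were deposited on another scale, with a median of 7078 in the treated and 7972 in the control column, against medians of 179.5 and 110.5 counts for the 32 genes above. Taken as deposited, their median log2 ratio was -0.14, with 19 lower, 10 higher and 2 equal in the treated library. If the values were scaled by library size like the other rows, the median would be -0.93, with 28 lower and 3 higher. Kept in the whole analysis, and so scaled by library size like counts, they moved the core list to -0.66, below the random range. With their ratio as deposited used in the lists instead, the core list stayed within the random range. Atg4a, a protease that processes ATG8 proteins, was listed at 2851 and 9633, a ratio of 0.296 as deposited. Atg13, a subunit of the ULK1 kinase complex, was listed at 6881 and 2949, a ratio of 2.33 as deposited. Map1lc3b (LC3B) had a ratio of 0.698, Becn1 0.805, Bnip3l 0.599 and Ulk1 1.36 as deposited. The unit of these rows is unknown, so no counting interval is given, and these ratios describe the deposited values only.

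**Figure D3:**
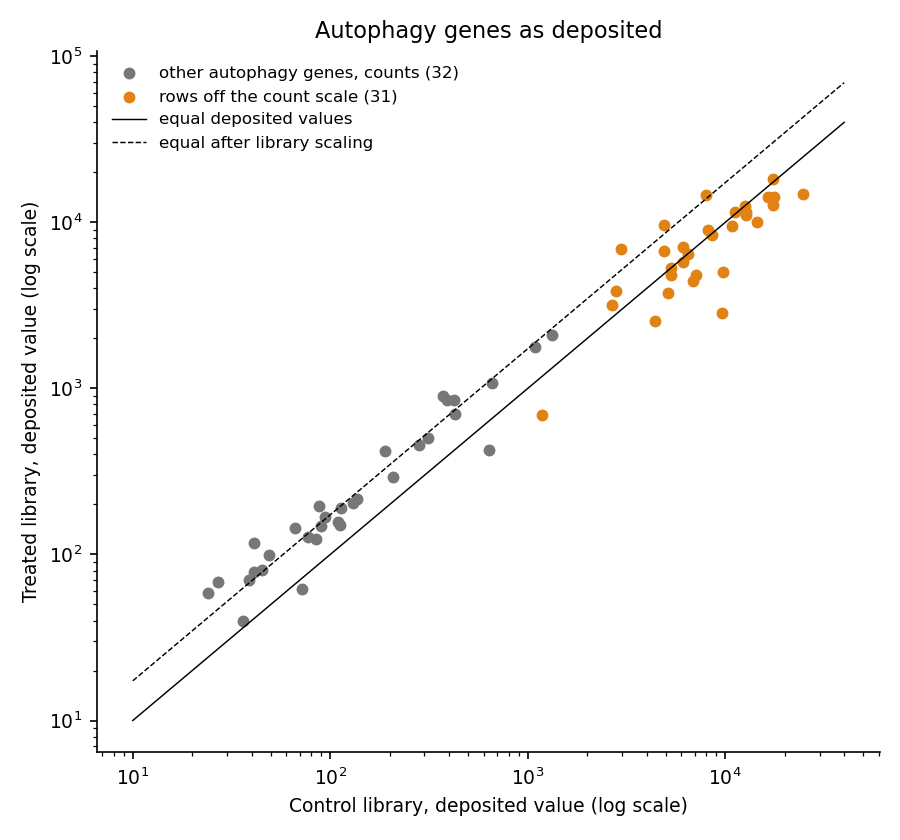
Deposited values of autophagy genes in the treated against the control column, on log axes. The 32 genes with counts are grey and the 31 rows off the count scale orange; the dashed line marks equal expression after library scaling and the solid line equal deposited values. The medians of the orange rows, 7078 and 7972, lie above those of the grey genes, 179.5 and 110.5.

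Among related degradation systems, the proteasome list was higher by a median log2 ratio of 0.25 (percentile 99.9), with 28 of 32 members above 0 and 2, Psmc5 and Adrm1, more than 2-fold higher. Psmc5, a subunit of the regulatory particle, was 2.15-fold higher (1.81 to 2.57). The lysosome list had a median of 0.05 (percentile 68.2) over 31 members and the ubiquitin ligase list 0.04 (percentile 58.9) over 22. Vhl, the substrate receptor of a ligase used by many degraders, was 2.36-fold lower (1.60 to 3.52).

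Neutrophil genes were higher in the treated library. Of 17 measured members of that list, 13 were at least 2-fold higher, and the median log2 ratio was 1.42, above all random lists. The calprotectin genes S100a8 and S100a9 were 2.47-fold (2.29 to 2.66) and 3.29-fold (3.07 to 3.53) higher, and the chemokine receptor Cxcr2 6.44-fold (2.81 to 18.2). S100a8 and S100a9 are also made by activated epidermis, whose genes were higher in the same library. Mmp9, a gelatinase stored by neutrophils, went the other way and was 4.62-fold lower (4.27 to 5.01). With a minimum mean of 50 CPM the list's median was 0.067 and no longer stood apart.

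Inflammatory and myeloid lists were higher as well. The NF-kB and inflammation list had a median of 0.54 (percentile 100) with 7 of 27 members at least 2-fold higher and 2 lower, but with a minimum of 50 CPM it was 0.26 and no longer stood apart. The neutrophil attractants Cxcl2 and Cxcl5 were 11.3-fold (8.22 to 15.9) and 7.16-fold (3.98 to 14.2) higher, and Il1b 2.74-fold (2.40 to 3.12). The macrophage list had a median of 0.36 (percentile 99.8), with 5 of 23 members at least 2-fold higher, but 0.13 with a minimum of 50 CPM, no longer apart. The share of counts on the macrophage list ran the other way, 0.568% (0.560% to 0.575%) in the treated and 0.774% (0.763% to 0.786%) in the control library, and abundant Spp1 and Lyz2 had log2 ratios of -0.93 and -0.66. The direction of this share rests on Spp1, by far the most abundant member with a mean of 4082 CPM. Spp1 is also on the epithelial-mesenchymal transition list. Lyz2 was named after its value was seen. The list of alternatively activated macrophages had a median of 0.55 (percentile 99.4) and a mean of 0.83. The scavenger receptor Cd163 was 9.88-fold higher (4.65 to 25.1) and the mannose receptor Mrc1 2.99-fold (2.52 to 3.57). Spp1 (osteopontin), a member of the macrophage list but not of this list, was 1.91-fold lower (1.86 to 1.96). Arg1, abundant in suppressive myeloid cells, had a ratio of 0.982 (0.898 to 1.07). Type I interferon genes had a median of 0.40 (percentile 99.99) with 24 of 28 above 0. Ifit3 was 2.79-fold higher (1.97 to 4.05), with the near-identical Ifit3b making both uncertain. Interferon-gamma targets lay within range at -0.06, with Cxcl9 2.24-fold lower (1.95 to 2.59) and Socs1 2.40-fold higher (1.79 to 3.26). MHC class I genes had a median of 0.07 and class II genes 0.19, both within range, and the invariant chain gene Cd74 was 2.11-fold higher (2.03 to 2.19).

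Lymphocyte genes were sparse at this depth. The plasma cell list was lower, with a median of -2.42 over 6 members, of which 3 were antibody genes or Jchain and 2, Sdc1 and Fkbp11, had ratios above 1. With no minimum the median was -0.79, and with totals without mitochondrial, haemoglobin and ribosomal protein genes -3.86. Only 2 T cell genes reached the minimum, and Thy1 and Cd3g had ratios of 0.991 (0.785 to 1.25) and 1.03 (0.613 to 1.78). The lists for regulatory T, cytotoxic, B, mast and Schwann cells, for secretory mammary epithelium and for replication histones also had fewer than 5 measured members and were not ranked. Gzma, a granzyme of cytotoxic and natural killer cells, was 4.81-fold higher (2.80 to 8.84). Immune checkpoint genes had a median of -0.07, within range, with the inhibitory receptor Tigit 2.46-fold higher (1.59 to 3.93). Dendritic cell genes lay within range at -0.13, but stood apart as higher at 0.33 with no minimum. The latter is the log2 ratio of a gene with a single treated count and no control count, at the counting floor.

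Stromal and vascular genes were lower in the treated library. Of 12 measured endothelial genes, 11 were below 0 and 5 at least 2-fold lower, with a median of -0.92 below all random lists. Cdh5 (VE-cadherin) and the tight junction gene Cldn5 were 3.17-fold (2.35 to 4.31) and 3.53-fold (2.19 to 5.83) lower. The list for myofibroblasts and pericytes had a median of -0.70 (percentile 0.05) over 6 genes, with Tagln 4.11-fold lower (3.45 to 4.91). With totals without mitochondrial, haemoglobin and ribosomal protein genes it was -0.25 and no longer stood apart. Epithelial-mesenchymal transition genes had a median of -0.53, below all random lists, although Vim differed by a ratio of 0.927 (0.891 to 0.964). Fibroblast and matrix genes were lower by a median of -0.25 (percentile 0.79), with members on both sides: Col3a1 had a ratio of 0.832 (0.781 to 0.885), whereas Col6a2 was 3.40-fold higher (2.11 to 5.77). With the mean of the list in place of the median, at -0.11, they no longer stood apart. All 5 measured adipocyte genes were lower, with a median of -2.54. The lipid-binding protein gene Fabp4 was 5.89-fold lower (5.08 to 6.85) and Cfd (adipsin) 7.16-fold (5.80 to 8.90).

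Other tissues also differed. Haemoglobin genes were higher, Hbb-bs by 3.24-fold (2.86 to 3.69), and the erythroid list had a median of 1.69 over 5 genes, or 0.33 with no minimum. The latter is the log2 ratio of a gene with a single treated count and no control count. The skeletal muscle list had a median of 0.57 (percentile 98.1) over 5 genes, with Tnnt3 4.16-fold higher (2.37 to 7.88) and Eno3 1.47-fold lower (1.25 to 1.74). That median is the log2 ratio of Pvalb, which had 5134 against 1996 counts, whereas Acta1 had 61 against 10. Whether Pvalb came from muscle here was not tested. The second sheet leaves out 14 genes of the muscle list, Tnnt3 among them, and the list could not be ranked on it, nor did it stand apart by its mean of 0.58; with totals without mitochondrial, haemoglobin and ribosomal protein genes the median was 0.93. The 4T1 epithelial list was higher, with a median of 0.60 and a mean of 1.18 over 24 genes. Its most abundant members Krt8 and Krt18 differed by 1.08-fold (1.04 to 1.12) and 1.13-fold (1.08 to 1.18), and Krt5 and Trp63, which it shares with epidermis, had the largest ratios. Without 5 members that are abundant in epidermis, a choice made after the data were seen, the median was 0.31 (percentile 99.7).

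Hypoxia-induced genes were lower, with a median of -0.61 below all random lists and 16 of 18 below 0. Ankrd37 was 3.85-fold lower (3.10 to 4.80), and the vasodilator peptide gene Adm was 3.43-fold higher (2.15 to 5.74). Glycolysis genes were lower by a median of -0.25 (percentile 2.4), a call that held in 7 of 13 alternatives, with Pgk1 2.15-fold lower (2.03 to 2.29) and Hk2 2.27-fold (1.80 to 2.86). Oxidative phosphorylation genes, at 0.13, and mitochondrially encoded genes, at 0.06, lay within range, the former just above it with the 31 autophagy rows kept. Fatty acid genes lay within range at -0.06, but stood apart as lower by their mean of -0.25, and Scd1, the stearoyl-CoA desaturase, was 4.05-fold lower (3.60 to 4.56). Of the 17 measured fatty acid genes, 3 were at least 2-fold lower, Scd1 among them, and 1 at least 2-fold higher. Cholesterol synthesis genes were higher by 0.33 (percentile 99.5), but did not stand apart with a minimum of 50 CPM (0.16) or by the mean of the list (0.29).

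Targets of the integrated stress response were higher, with a median of 0.62 above all random lists and 4 of 16 members at least 2-fold higher. Asns, asparagine synthetase, was 2.76-fold higher (1.95 to 4.01), whereas Atf4, the transcription factor of this response, had a ratio of 0.732 (0.655 to 0.817) and Ddit4 was 2.59-fold lower (2.20 to 3.06). Among the members with a mean of at least 50 CPM the median was -0.31, and by its mean of 0.48 the list did not stand apart. Unfolded protein response genes were higher by 0.30 (percentile 99.3), with the chaperone Hspa5 1.68-fold higher (1.59 to 1.78). The NRF2 list was higher by 0.30 (percentile 98.5) and the ferroptosis list, which shares the ferritin genes with it, by 0.27 (percentile 98.2). By the mean of the list, the unfolded protein (0.23), NRF2 (0.27) and ferroptosis (0.15) lists did not stand apart. Fth1 was 1.36-fold higher (1.32 to 1.40). Heat shock, cell death and p53 target lists lay within range at 0.17, 0.22 and 0.07, and the small heat shock gene Hspb1, which epidermis expresses too, was 9.47-fold higher (4.45 to 24.1).

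Genes of the G2 and M phases were higher by a median of 0.30 (percentile 99.8), with 26 of 31 above 0 and Cdc20 2.13-fold higher (1.62 to 2.83). S phase genes lay within range at 0.14, and Pcna had a ratio of 0.998 (0.890 to 1.12). MYC targets were higher by 0.36 (percentile 99.9), with 21 of 22 above 0 and the spermidine synthase gene Srm 3.23-fold higher (2.48 to 4.27). Ribosomal protein genes had a median of -0.15, within range but below that of unmatched random lists, and held 9.68% of treated (9.65% to 9.70%) and 10.9% of control counts (10.9% to 11.0%). Immediate early genes were higher by 0.34 (percentile 99.3), with Klf4, also an epidermal factor, 3.82-fold higher (2.54 to 5.96), but did not stand apart with a minimum of 50 CPM (0.18) or by the mean of the list (0.40), while with no minimum the median was 0.65.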

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

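The tests of library depth, of both accounts of the 31 autophagy rows and of the neutrophil list without epidermal genes were chosen after the results were seen. Those of skin cell types and of platelet genes were set before their values were seen.

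The second deposited sheet, whose name says that errors were removed, differs from the full one and was used only as an alternative. It leaves out 40 genes, 14 of them in the skeletal muscle list and 2 in the keratinocyte list, and the summed counts of those genes were 2797 in the treated and 495 in the control library. Without Krtdap, Sbsn, Lce1c and Zmat2, which carry most of these sums, they were 686 and 273. For 3 epidermal genes its control value is above that of the full sheet: Dsc3 has 89 in place of 0, Krt79 99 in place of 1 and Pof1b 99 in place of 2. Their treated values, 200, 215 and 213, are equal in both sheets. No explanation of these differences was tested.

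Epidermal genes were higher in the treated library. A difference in library depth is argued against as the cause, since the keratinocyte list had 6434 counts against 86, an unscaled ratio of 74.8 (60.5 to 93.7), while the library totals had a ratio of 1.70. Skin collected with the treated tumour remains a candidate explanation: genes of Langerhans cells, melanocytes, hair follicles and sebaceous glands, which stratified keratinocytes do not need, had 27 counts against 7, a ratio of 2.22 with an interval of 0.945 to 6.05, which does not decide. Within that pool, hair follicle and sebaceous genes had 14 counts against 1, a ratio of 8.07 (1.23 to 341), and Langerhans cell and melanocyte genes 13 against 6, a ratio of 1.25 (0.443 to 4.01). Squamous differentiation of tumour cells under treatment stays open and untested, as does a difference between the batches, which cannot be told apart from treatment.

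The 31 autophagy rows were off the count scale. In all 31 rows, treated and control values lay on a common step, which unrounded values scaled to each library's size would not show. Values rounded after such scaling and then multiplied by a common number could share a step too. The step therefore does not decide whether the rows were already scaled. A factor per gene would leave the ratio of the columns unchanged, so a ratio cannot test such a factor by itself. The median unscaled log2 ratio was -0.14, outside the range of 0.64 to 1.03 for random lists of 31 other genes. That range comes from unscaled counts, so it applies only if the 31 rows were not already scaled by library size. In that case, the value argues only against rows whose ratios, apart from such a factor, were like those of other genes. It stays open whether transcripts of these genes may have been fewer in the treated tumour, or whether the rows came from another measurement or another scaling. The 32 other autophagy genes, which kept their counts, had a median scaled log2 ratio of -0.07.

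Neutrophil genes were higher in the treated library, and genes that epidermis also expresses were not the whole of it, since the list without them had a median log2 ratio of 1.27, above the random range of -0.33 to 0.45, with 7 of its 9 measured genes above 0. The summed counts of that list went the other way, 1963 against 2649, a ratio of 0.427 (0.403 to 0.453), and Mmp9 held 859 and 2290 of them. More blood in the treated tumour could not be decided, since haemoglobin genes were higher but platelet genes had 13 counts against 11, a ratio of 0.681 (0.282 to 1.68), whose upper bound lies below the neutrophil list's median fold of 2.67. That bound, set before, was wrong as a criterion because the median platelet gene had 0 treated and 0.5 control counts, at the counting floor. An influx of neutrophils with treatment or with wounded skin stays open and untested.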

How the results depend on the processing

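Alternatives that keep the 31 rows or leave out epidermal genes or list members were added after the data were seen. No paired analysis was possible because each group has 1 library. Of the 18 lists that stood apart as higher, 8 did so under every alternative that could rank them, as did 5 of the 8 lower ones. Of the 17 others, 12 stayed within range. Those 13 include keratinocyte, erythroid, proteasome, MYC, type I interferon, adipocyte, plasma cell, endothelial and hypoxia genes. Their size could still move: with no minimum the erythroid median was 0.33 and that of plasma cells -0.79, against -3.86 for plasma cells with totals without mitochondrial, haemoglobin and ribosomal protein genes. The erythroid value of 0.33 is that of a single treated count against none. The largest shift of the median of all genes under another scaling was 0.0304. With a minimum of 50 CPM, 9 lists had too few members to rank, and so had skeletal muscle with the second sheet and with the 31 rows kept as deposited. The 9 include the erythroid, alternatively activated macrophage, adipocyte, plasma cell and endothelial lists, whose calls were therefore not checked at that minimum. Control depth, where 1 count is 0.449 CPM, limits the folds of epidermal genes with few control counts. The cause of the changes below was not tested except where fewer or more genes were counted.

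The number of higher and lower genes was 1061 and 674 with a minimum of 1 CPM, 1356 and 774 with none, 81 and 77 with 50 CPM (51.3% higher), and 1138 and 800 at 1.5-fold. A pseudocount of 5 gave 144 lower genes. Pearson's r was 0.95 with no minimum and Spearman's rho 0.84 with 50 CPM. With a minimum of 50 CPM, the medians of cholesterol synthesis (0.16), immediate early (0.18), macrophage (0.13), neutrophil (0.067) and NF-kB genes (0.26) no longer stood apart, and that of the integrated stress response turned to -0.31. With the mean of the list, cholesterol synthesis (0.29), ferroptosis (0.15), fibroblast (-0.11), immediate early (0.40), integrated stress response (0.48), NRF2 (0.27), skeletal muscle (0.58) and unfolded protein genes (0.23) no longer stood apart, and fatty acid genes (-0.25) did. Glycolysis lost its place at -0.24 without mitochondrial, haemoglobin and ribosomal protein genes in the totals, at -0.22 with a minimum of 1 CPM or none, at -0.25 with 50 CPM, and at -0.25 both with the 31 rows kept and with their ratio as deposited in the lists. Totals without those genes also ended the call of myofibroblasts and pericytes (-0.25). With unmatched random lists, ferroptosis (0.27) no longer stood apart and ribosomal proteins (-0.15) did. With no minimum, dendritic cell genes turned to 0.33, the value of a single treated count against none. Keeping the 31 rows as deposited, and thus scaled by library size like counts, moved the core autophagy list to -0.66, below the random range. With their ratio as deposited in the lists, its median was -0.07 (percentile 46.2), within that range. Both alternatives moved oxidative phosphorylation to 0.13, just above the range. Scaled by library size, the 31 rows had a median of -0.93. Of the named genes, 22 values moved beyond their counting interval, each with a pseudocount of 5, and 1487 did not.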

Other observations

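The test of YAP targets was chosen after part of its values were seen, and the genes named here outside the rule were picked after their values were seen.

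The proliferin genes Prl2c2 and Prl2c3, prolactin-family hormones with near-identical copies, had 217 and 1066 counts in the treated library against 2 and 10 in the control, ratios of 62.6 (17.1 to 520) and 61.5 (33.3 to 129). Which copy the reads came from is uncertain. In the other direction, Gphn, Lars2, Camk1d, Cmss1 and Cdk8 were lower in the treated library by 4.08-fold (3.73 to 4.47), 3.20-fold (2.94 to 3.48), 3.10-fold (2.60 to 3.70), 2.29-fold (2.16 to 2.44) and 2.23-fold (2.09 to 2.37). These are genes in which reads of ribosomal RNA-like sequence can be counted, so their values need not reflect their own transcripts. A check on 3 noncoding genes that overlap ribosomal RNA repeats, set before their values were seen, could not be run.

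Ccn2 and its relative Ccn1, lower by 9.92-fold and 2.23-fold (1.87 to 2.65), are targets of the mechanosensitive coactivators YAP and TAZ. A list of 22 such targets had a median log2 ratio of -0.49 over 19 measured genes, with 15 below 0. Without Ccn2, Igfbp3, Rbms3 and Ccdc80, whose values prompted the test, the median was -0.45, below the random range of -0.23 to 0.31. Lower YAP and TAZ target expression in the treated tumour is consistent with this value, as a hypothesis. Fewer endothelial and pericyte cells, whose genes were lower too, could give the same result, and this was not tested.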
